A study of Drosophila melanogaster with 3 samples.

How the data were processed

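ChIP-seq peak lists were taken for 3 biological replicates of transgenic Drosophila melanogaster embryos expressing Mrtf fused to eGFP, precipitated with anti-GFP. Per the labels, chromatin was fragmented by sonication to 200 to 800 bp, embryos were aged 0 to 24 h, and the assembly was dm6. The aligner, the peak caller and their versions are not given in the sources used here. Per the labels, a separate experiment is a possible control, and its data are not used here. Per the deposited descriptions, each list was derived from the alignments of 1 replicate or of all 3, together with further files whose content is not stated, so it is not known how background was subtracted. The lists of single replicates allow the replicates to be compared. The whole-series lists are pooled and have no replicates of their own.

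Each deposited peak carries a signal value given by the authors' peak caller, which is never negative and larger for stronger peaks. Its scale against read depth is not stated, so the authors' signal was used only to rank and filter peaks within a list, and to express a peak as a multiple of the median of the same replicate's list. In the whole-series lists a peak has the same signal in each list, so this value is pooled. The deposited ranked lists also hold the irreproducible discovery rate (IDR) as −log10, capped by the authors. The 7 thresholded lists were checked against their 7 ranked lists. Each peak in them had a global IDR of at most 0.01, but not all such peaks were kept (2643 of 2736 for the conservative list over all sequences), and the rule that removed the rest is not stated. Which replicates each whole-series list compares is not stated either, so these are named by size.

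Peaks on the arms X, 2L, 2R, 3L, 3R, 4 and Y were used. The ends of all peaks lay within the arm lengths of the reference. Genes came from the Ensembl annotation, release 115, of the same assembly. A summit within 500 bp of a start of any annotated transcript was called a promoter, and other summits were assigned in the order 5' untranslated region, coding exon, 3' untranslated region, intron and intergenic. Entries for transposable elements (5889 of 24166) counted as transcript starts and in the background of all genes, but were not named as the nearest gene. Keeping them in that background was settled after both values had been seen.

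The overlap of replicate lists (at least 1 bp) and the annotation classes were compared with 1000 random placements on the same arms, two-sided. Gene lists were compared with 13968 protein-coding genes, and tRNA, snRNA and snoRNA genes with all annotated entries, by two-sided Fisher's exact test with Benjamini-Hochberg adjustment over 22 lists, of which 1 is not reported here. The 95% intervals of odds ratios add 0.5 to each count. The lists were actin genes, actin filament assembly and turnover, non-muscle myosin and contractility, integrin adhesion, sarcomere proteins, SRF and Mrtf cofactors, tracheal development, epithelial junctions, the Hippo pathway, patterning and muscle transcription factors, neuronal differentiation, heat shock, DNA replication and mitosis, ribosomal proteins, the proteasome, histones, odorant and gustatory receptors, cuticle proteins, tRNA genes, and snRNA and snoRNA genes. Of the listed symbols 9 had no match in the annotation and 3 were matched through an older name. Motifs were searched on both strands in windows reaching 100 bp to each side of the summit and in windows of the same size centred 1000 bp to each side. Summit and right-hand windows were compared by exact two-sided McNemar tests, adjusted over 18 motifs, and the flank percentage is the mean of both sides. The 95% limits of motif differences are for summit minus right-hand window. At Mrtf, peaks in the gene and 20 kb on each side were compared with the density of the arm and with 1000 random windows. The threshold was 0.05.

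The designs, lists and motifs of the main analyses and the rule for named genes were fixed before the data were examined, except the random windows at Mrtf and the handling of transposable elements. Some alternative settings were added afterwards, as named in the part on other settings. Named were the 25 strongest conservative peaks with the nearest gene and any other gene within 500 bp, the first 4 bound and first 2 unbound members of each list, and Mrtf and bs. A peak's multiple of the median was given as mean and SD only where the ranked lists of all 3 replicates had an overlapping peak. Read depth is unknown, so no interval that needs it was given, and because all samples form 1 group no test between groups was made. The gene list, motif and annotation procedures were tested on simulated data. With summits placed at a start of random protein-coding genes, 10 of 1000 tests of the protein-coding gene lists were called. A list made to be enriched was recovered, and 100 of 100 planted motif sites were found. Each random gene gave only 1 summit, so a bias towards genes with many transcript starts was not checked.

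Alternatives were other whole-series lists, the peaks in all 3 replicate lists, a stricter signal threshold, other windows, other backgrounds and gene assignments, other definitions of a shared peak, and each replicate left out. Python 3.11.15, NumPy 2.4.6, pandas 2.3.3, SciPy 1.17.1 and Matplotlib 3.10.9 were used. Peaks on unplaced scaffolds were left out of the comparisons.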

Results

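The data were chromatin immunoprecipitation and sequencing (ChIP-seq) peak lists from whole Drosophila melanogaster embryos aged 0 to 24 h. The embryos carried a transgene encoding Mrtf fused to enhanced green fluorescent protein (eGFP), and an antibody against GFP was used for the precipitation. Mrtf is the fly myocardin-related transcription factor, a coactivator that works with serum response factor (SRF, encoded by bs) and is kept out of the nucleus by unpolymerised actin. All 3 samples were biological replicates of 1 group, so no comparison between groups was possible, and what was asked was where the tagged protein was found in the genome and how far the replicates shared those sites. Each replicate had its own thresholded peak list, and 4 further thresholded lists were derived from all 3 replicates. The number of sequenced reads behind each list is not given in the sources used here, so the depth is unknown. Coordinates are those of the dm6 assembly.

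The replicates placed their peaks at largely the same sites. On the main chromosome arms replicate 1 had 1735 peaks, replicate 2 had 2373 and replicate 3 had 1519, a mean of 1876 ± 444 (SD, n = 3). The largest replicate list was 1.56 times the smallest. Of the peaks of replicate 1, 78.3% overlapped a peak of replicate 2 by at least 1 bp and 60.5% a peak of replicate 3. Of the peaks of replicate 2, 57.8% were shared with replicate 1 and 53.7% with replicate 3. Replicate 3 shared 68.7% of its peaks with replicate 1 and 83.5% with replicate 2. Peaks placed at random on the same arms overlapped in at most 1.78% in any of 1000 placements. The two-sided permutation p by random placement was 0.002 for each of the 6 comparisons, the smallest that 1000 placements can give. Across the shared peaks the signals ranked alike, with a mean Spearman correlation of 0.71 ± 0.06 (SD, n = 3 pairs of replicates). This correlation is across peaks, which are not independent replicates, so it has no p-value. The closest pair was replicates 2 and 3, at 0.78 over 1275 shared peaks.

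The main list for what follows was the conservative list of the whole series, which held 2640 peaks on the main arms with a median width of 336 bp. It contained 90.7% of the peaks of replicate 1, 79.1% of replicate 2 and 83.9% of replicate 3, a mean of 84.6%. In turn, 1005 of its peaks (38.1%) lay in all 3 replicate lists, 605 in exactly 2 of them, 571 in 1 and 459 in none. The other whole-series lists had 3997, 2299 and 1868 peaks on the main arms, and 60.7%, 80.6% and 93.5% of these were in the conservative list. The largest of them was 1.51 times as long as the conservative list.

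The strongest sites were mostly promoters, among them those of Ugalt, CG14100 and mRpL41. Of the 25 conservative peaks with the highest signal, 17 had their summit within 500 bp of a transcript start, 6 lay in introns and 2 were intergenic, and all 25 were in the lists of all 3 replicates. In each replicate the signal was expressed relative to the median of that replicate's own list. The first peak, at X:2703722-2704059, had its summit 41 bp from a start of Ugalt (the Golgi UDP-galactose transporter) and stood at 14.9 ± 1.51 times the median (SD, n = 3). The next, at 3L:19590460-19590779, was 90 bp from a start of CG14100, at 13.3 ± 1.66 times the median. The third, at 2R:15217606-15217905, was 146 bp from a start of mRpL41 (a protein of the large mitochondrial ribosome subunit) and within 500 bp of lncRNA:CR44463, so the gene is ambiguous. It stood at 10.5 ± 2.20 times the median.

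Of these 25 peaks, 11 lay within 500 bp of more than 1 gene, so that neither gene can be assigned alone. CG7601 and CIA30 (an assembly factor of respiratory complex I) shared a peak at 10.8 ± 1.18 times the median (SD, n = 3). Tcs5 (a kinase of the complex that modifies tRNA) and CHMP2B (a subunit of ESCRT-III, which cuts membranes) shared another, at 9.71 ± 1.19. The pair asRNA:CR45928 and eIF6 (a factor for the large ribosomal subunit) was at 8.79 ± 1.03, and Art3 (an arginine methyltransferase) with mRpS10 at 8.48 ± 2.29. CenG1A (an Arf GTPase-activating protein) with mRpS23 was at 8.56 ± 1.18, Chro (a chromodomain protein of interbands and the spindle) with Ssl1 (a subunit of TFIIH) at 7.45 ± 1.32, and mRpL23 with CG9004 at 6.5 ± 1.34. Mtl (a small GTPase) shared its peak with CG5611, at 6.81 ± 1.43, Atat (an alpha-tubulin acetyltransferase) with Shc (an adaptor of receptor tyrosine kinases), at 6.41 ± 1.24, and Elp5 (a subunit of Elongator) with CG1275, at 5.98 ± 1.65. Singled out after the values were seen, 4 genes for mitochondrial ribosomal proteins (mRpL41, mRpS10, mRpS23 and mRpL23) lay beside peaks of this set.

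Among the single-gene promoters of the set were PNPase (the mitochondrial polynucleotide phosphorylase), at 7.67 ± 1.55 times the median (SD, n = 3), px (plexus, named for its wing vein phenotype), at 7.13 ± 1.26, CG1888, at 6.46 ± 0.134, and lncRNA:CR44619, at 6.35 ± 2.09. The 6 intronic peaks had CG11050, ph-p (polyhomeotic proximal, a Polycomb group protein), Adf1 (a sequence-specific transcription factor), CG32772, HmgZ (an HMG-box chromatin protein) and CG3726 as the gene of the nearest start, at most 1751 bp away. Their signals ran from 9.88 ± 3.63 times the median at CG11050 to 5.89 ± 1.2 at CG3726. The intergenic peaks lay 909 bp from lncRNA:CR45643, at 7.40 ± 1.16, and 11922 bp from CG13323, at 6.80 ± 1.29. The plot of the strongest peaks gives the values of each replicate.

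**Figure D1:**
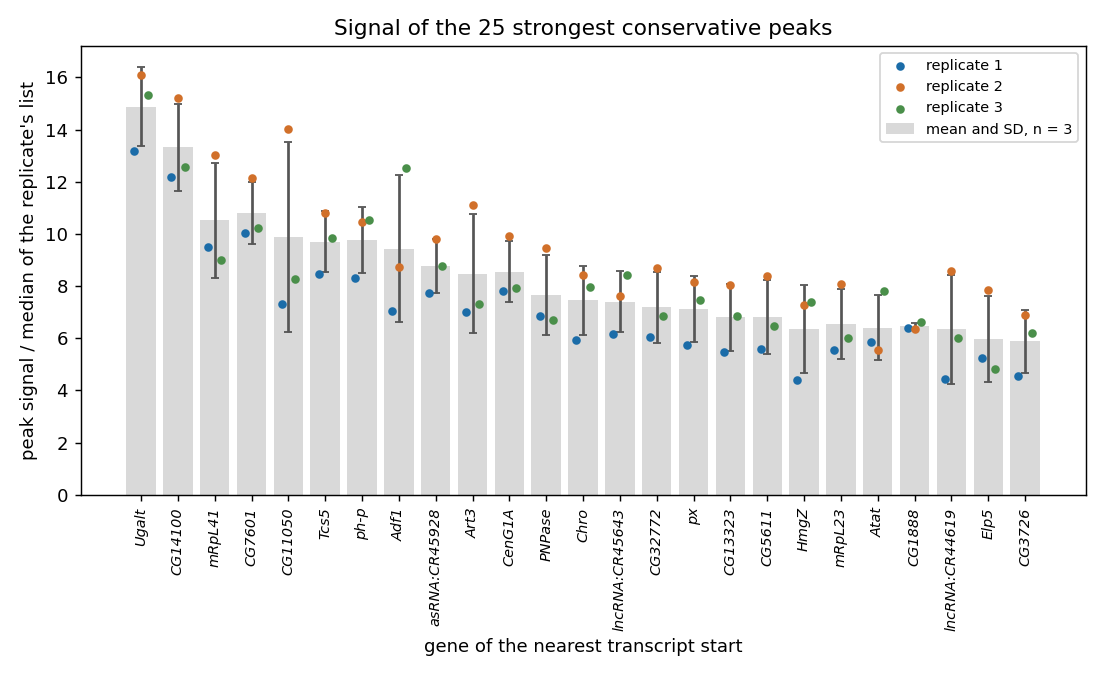
Peak signal divided by the median signal of the replicate's own thresholded list, for the 25 conservative peaks of highest signal, named by the gene of the nearest transcript start. Bars are means and error bars SDs over 3 replicates, points are replicates. The means fall from 14.9 at Ugalt to 5.89 at CG3726.

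Peaks gathered at promoters and were scarce in exons. In the conservative list 1340 of the 2640 summits (50.8%) lay within 500 bp of an annotated transcript start, against 16.6% ± 0.718 (SD over 1000 placements) for summits placed at random on the same arms, a 3.06-fold excess. In the replicate lists the share was 56.2%, 50.5% and 48.3%, a mean of 51.7% ± 4.10 (SD, n = 3). Coding exons outside promoters held 0.985% of the summits against 13.6% at random, and 3' untranslated regions 1.10% against 4.32%. Introns held 33.6% against 41.1%, and intergenic sequence 13.1% against 23.7%. Each of these 5 differences had a two-sided permutation p of 0.002 by random placement, the smallest the 1000 placements can give, and each had the same direction in all 3 replicate lists. The 5' untranslated regions outside promoters, at 0.455% against 0.774%, did not pass the threshold (permutation p = 0.054). Of the 1324 summits within 500 bp of a gene's start, transposable elements left out, 81.2% lay upstream, with a median position 99 bp upstream. The fold narrowed or widened with the window, to 4.82 at 200 bp and 2.20 at 1000 bp.

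**Figure D2:**
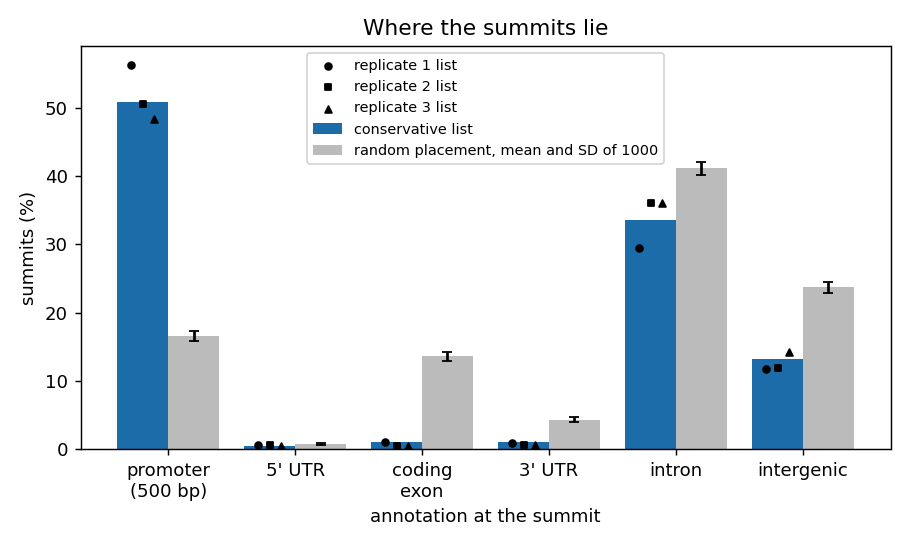
Share of summits in each class of annotation, in percent. Blue bars are the conservative list, grey bars the mean of 1000 random placements with SD, and points the 3 replicate lists. Promoters hold 50.8% of summits against 16.6% at random, and coding exons 0.985% against 13.6%.

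The X chromosome carried somewhat more peaks than its length and chromosome 4 far fewer. The X held 518 conservative peaks, 19.6% of the list on 17.1% of the length, a ratio of 1.15. In the replicate lists this ratio was 1.2 ± 0.0712 (SD, n = 3) and above 1 in 3 of 3. Among the unthresholded peaks of the replicates it was 0.95 ± 0.0561 (SD, n = 3). In the largest of the other whole-series lists the ratio was 1.04, and in the peaks present in all 3 replicate lists it was 1.35. Arms 2L, 2R, 3L and 3R had ratios of 1.08, 0.944, 1.07 and 0.971. Chromosome 4 held 3 peaks, a ratio of 0.116, and chromosome Y held 0. In the unthresholded lists chromosome 4 was as sparse, at 0.114 ± 0.112 (SD, n = 3). These ratios were not tested.

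To ask which kinds of genes carried peaks, gene lists fixed before the data were examined were tested, and 21 of them are reported. A gene was counted as bound when a summit lay within 500 bp of any of its transcript starts. In the conservative list 1608 of 13968 protein-coding genes were bound (11.5%), and in the replicate lists 8.63% ± 1.92 (SD, n = 3). The share was higher in 4 lists, lower in 4 and did not pass the threshold in 13. Adjusted p-values are from two-sided Fisher's exact tests with Benjamini-Hochberg adjustment over all 22 lists tested.

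Among the reported lists cytoplasmic ribosomal protein genes had the largest share of bound members in the conservative list. Of 92 genes 43 (46.7%) had a peak, an odds ratio of 6.90 (95% interval 4.58 to 10.4, exact adjusted p = 6.42e-16). The replicate lists bound 44, 36 and 17 of them, with odds ratios of 9.92, 5.59 and 3.21 and adjusted p-values of 1.57e-21, 1.16e-11 and 0.00238 by Fisher's exact test. In replicate 3 the share was larger in the Hippo list, at 3 of 14 genes against 17 of 92. Within 1000 bp the myosin and Hippo lists each had 7 of 14 bound, against 44 of 92 ribosomal protein genes. RpS27 (a small subunit protein, FBgn0039300) had a peak at 3R:25247414-25247614 with its summit 3 bp from a start, shared with Nup37 (a nucleoporin) and sisRNA:CR46364, at 2.40 ± 0.535 times the list median (SD, n = 3). RpL34b shared its peak with CG8132 (2.20 ± 0.0759), RpL7 with Ripalpha (2.0 ± 0.376) and RpS21 with CG3104 (1.77 ± 0.781), so these are ambiguous between neighbours. Unbound members included RpL10 and RpL10Aa. Of the 43 bound genes 15 had their peak in all 3 replicate lists, and 28 shared it with another gene. Among genes that share no promoter window with a neighbour, 4 of 21 ribosomal protein genes were bound and the call ended (odds ratio 3.51, exact adjusted p = 0.175).

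With any transcript start counted, the lists of actin filament assembly and of non-muscle myosin genes passed the threshold as bound more often in the conservative list. The actin genes themselves did not. For actin filament assembly and turnover 13 of 48 genes were bound (27.1%, odds ratio 2.87, exact adjusted p = 0.00872), with 6, 9 and 7 in the replicate lists. Fhos (a formin, FBgn0266084) had the strongest of these peaks, in an intron at 3L:8766072-8766267, at 2.79 ± 0.968 times the median (SD, n = 3). It was followed by pod1 (a coronin family protein that links actin and microtubules), at 0.991 ± 0.179, and by Hem (a subunit of the WAVE complex), at 1.05 ± 0.355, which shared its peak with IleRS. Next was coro (coronin), at 0.878 ± 0.205, which shared its peak with asRNA:CR44169. Abi (another WAVE complex subunit) and Actn (alpha-actinin) were unbound.

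Of the 14 genes for non-muscle myosin and contractility 5 were bound (35.7%, odds ratio 4.28, exact adjusted p = 0.0403). They included jar (myosin VI), at 1.39 ± 0.0889 times the median (SD, n = 3), and sqh (the regulatory light chain of non-muscle myosin II), at 1.23 ± 0.483. Myo95E (an unconventional myosin) shared its peak with TBC1d7, at 0.891 ± 0.329, and Rok (a kinase that acts on the myosin machinery) shared its peak with the ribosomal protein gene RpS19a, at 0.736 ± 0.508. Mbs (a subunit of myosin phosphatase) and Mlc-c (a myosin light chain) were unbound.

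Genes of the Hippo pathway, which controls tissue growth, and its targets were bound in 5 of 14 cases (35.7%, odds ratio 4.28, exact adjusted p = 0.0403). The members were led by Mer (merlin, at 1.24 ± 0.176 times the median, SD, n = 3), mats (a kinase cofactor, at 1.14 ± 0.302), yki (the pathway's coactivator, at 0.851 ± 0.135, with a peak shared with Gpat4) and hpo (the founding kinase, at 0.580 ± 0.206). Diap1 and ds were unbound. Of these 3 lists (actin filaments, myosin and Hippo) only the myosin list passed the threshold in any replicate list (replicate 2, exact adjusted p = 0.0356 by Fisher's exact test). With the peaks present in all 3 replicate lists the odds ratios were 1.62, 2.97 and 4.86 and did not pass, but only 4, 2 and 3 genes were then bound. Among genes that share no promoter window with a neighbour the actin filament list still passed (6 of 17 bound, odds ratio 8.19, exact adjusted p = 0.00916). There only 2 myosin and 6 Hippo genes remained, with 1 bound in each list. Neither list passed (odds ratios 14.9 and 2.97, exact adjusted p = 0.336 and 0.582). So few genes cannot show whether shared promoters made these 2 calls. The actin filament call ended in other settings, such as 200 bp (odds ratio 2.31, exact adjusted p = 0.146). With annotated gene starts only, and the same peaks and genes, none of the 3 lists passed. The odds ratios were then 1.82, 2.47 and 2.47 (exact adjusted p = 0.287 for each). A bias towards genes with many transcript starts is therefore not excluded for these 3 lists.

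Adhesion, sarcomere, actin and SRF cofactor genes did not pass the threshold as groups in the main analysis. When each peak was given to the nearest start within 10 kb all 4 passed as higher, with odds ratios of 3.84, 3.41, 6.81 and 13.6 (exact adjusted p = 0.00600, 0.0145, 0.0490 and 0.00652). The last rests on 4 of 6 genes, among them the tagged gene Mrtf, whose peaks may come from extra copies of the locus. Gene length and spacing were not taken into account in this setting. Integrin adhesion and basement membrane genes were bound in 6 of 25 cases (exact adjusted p = 0.120), among them Pax (paxillin, 2.05 ± 0.635 times the median, SD, n = 3, with a peak shared with Alp12 and CG13085), by (tensin, 1.18 ± 0.598), CAP (a vinculin-binding adaptor, 1.07 ± 0.0748) and Vinc (vinculin, 0.988 ± 0.271), and not Col4a1 or Fak. Sarcomere genes were bound in 4 of 24 cases (exact adjusted p = 0.452), namely Msp300 (a giant nesprin, 2.41 ± 0.214), sls (a titin relative, 1.19 ± 0.485), Mlc2 (0.601 ± 0.297) and Mhc (0.380 ± 0.280), and not Clic or Mf. Of the 6 actin genes only Act5C was bound (exact adjusted p = 0.586), in the list of 1 replicate. Act42A and Act57B were not, although Act57B had a peak in the list of 1 replicate, and 2 actin genes were bound in that of replicate 2. Of the 6 SRF and Mrtf cofactor genes bs and Mrtf were bound (exact adjusted p = 0.218) and Mef2 and aop were not. The peak at bs (blistered, FBgn0004101), in the 5' untranslated region at 2R:24343467-24343802, was weak at 0.463 ± 0.158 times the median (SD, n = 3) and was in 0 of the 3 replicate lists.

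Lists of embryonic patterning and differentiation genes did not pass the threshold in either direction. Their odds ratios were below 1 for the patterning, tracheal, muscle and neuronal lists, and above 1, still without passing, when each peak was given to the nearest start within 10 kb (1.82, 2.27, 2.92 and 1.13). In the list of patterning transcription factors 1 of 38 had a peak (bcd, the anterior determinant, 1.18 ± 0.305 times the median, SD, n = 3), and Abd-B and Antp had none (exact adjusted p = 0.218). The tracheal list had 1 of 20 (bs again, with Cht2 and bnl unbound, exact adjusted p = 0.721) and the muscle transcription factors 1 of 20 (tin, a heart factor, with Doc1 and Doc2 unbound, exact adjusted p = 0.721). The neuronal list had 1 of 21, elav (a neuronal RNA-binding protein, 3.04 ± 1.05, sharing its peak with lncRNA:enrr), with ChAT and Dscam1 unbound (exact adjusted p = 0.586). Epithelial junction and polarity genes had 4 of 26 (exact adjusted p = 0.586), namely par-6 (1.18 ± 0.276, shared with CG8188), dlg1 (1.05 ± 0.183), cno and crb, with Atpalpha and Cont unbound. Heat shock genes had 4 of 18 (exact adjusted p = 0.218), with Hsp27 at 3.30 ± 0.754, Hsc70-4 at 1.16 ± 0.164 (shared with tefu), Hsp83 at 1.07 ± 0.322 and Hsp26 at 0.621 ± 0.134, and CG4456 and DnaJ-1 unbound.

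DNA replication and mitosis genes had 6 of 30 bound (exact adjusted p = 0.218). The first 4 were RnrS (the small ribonucleotide reductase subunit, 1.48 ± 0.497 times the median, SD, n = 3, shared with CG34231), Mcm2 (0.903 ± 0.239, shared with RPA1), dpa (Mcm4, shared with didum) and dup (Cdt1, 0.572 ± 0.102, shared with SRPK), and Cdc6 and Cdk1 were unbound. Proteasome subunit genes had 2 of 48 bound (exact adjusted p = 0.231), Prosbeta2 (shared with mRpL39) and Rpn6 (shared with ave), while Prosalpha1 and Prosalpha1R had none. No peak lay at any of 119 odorant and gustatory receptor genes, among them Gr10a and Gr10b (exact adjusted p = 8.32e-06), nor at any of 93 cuticle protein genes, among them Cpr100A and Cpr11A (exact adjusted p = 1.01e-04). The 111 histone genes, among them His1:CG31617 and His1:CG33801, also had 0 bound (exact adjusted p = 2.15e-05). These histone genes had no unthresholded peak in all 3 replicates either, whereas 47 of the receptor genes and 41 of the cuticle genes did. For histone genes a lack of binding therefore cannot be told apart from sequence where peaks could not be called.

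Against 24166 annotated entries tRNA genes were bound less often (5 of 290, odds ratio 0.218, exact adjusted p = 1.01e-04). Each of the 5 shared its peak with another gene, such as tRNA:Tyr-GTA-1-8 with CG8036, tRNA:Phe-GAA-1-2 with RpL17 and a snoRNA, tRNA:Trp-CCA-2-2 with CG30122 and tRNA:Leu-TAA-2-1 with CG13605, and tRNA:Ala-AGC-1-1 and tRNA:Ala-AGC-2-1 were unbound. The snRNA and snoRNA genes had 13 of 301 bound and did not pass the threshold (exact adjusted p = 0.0985). They passed as lower in replicate 2 (exact adjusted p = 0.0122) and in 4 alternative settings, such as without transposable elements in the background (odds ratio 0.423, exact adjusted p = 0.00370), and within 1000 bp the odds ratio was 1.40 without passing. The first were snoRNA:Psi28S-2949 (shared with Uhg4), snoRNA:Or-CD11a (with RpL28 and eIF1), snoRNA:U49:66Da (with RpL14 and Nelf-E) and snoRNA:Me28S-A774b (with RpS12), and scaRNA:MeU1:95C-A24 and scaRNA:MeU1b-A234 were unbound. With only genes that had an unthresholded peak in all 3 replicates as the background, the tRNA call ended (exact adjusted p = 0.244).

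**Figure D3:**
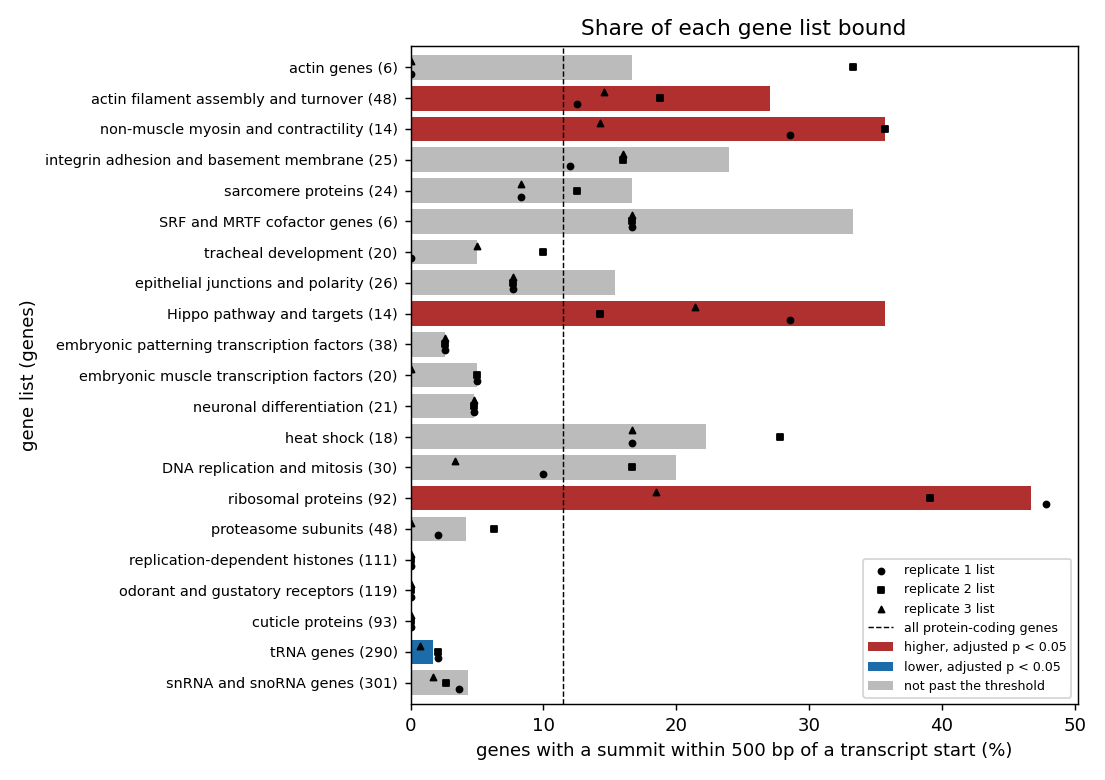
Percent of the genes of each list with a summit within 500 bp of a transcript start in the conservative list, with the number of genes in brackets and points for the 3 replicate lists. Red bars are higher and blue bars lower than the background at an adjusted p under 0.05 (Fisher's exact test). Ribosomal protein genes stand highest, at 46.7%, and the lists of histone, receptor and cuticle genes are at 0 and also passed the threshold. Histone genes had no unthresholded peak in all 3 replicates, so their 0 may not reflect a lack of binding.

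The sequence that SRF binds, the CArG box, was no more frequent at the summits than beside them. Within 100 bp of the summit 23 of 2640 peaks (0.871%) held a match to CCWWWWWWGG, where W is A or T, against 1.5% of windows centred 1000 bp away (exact two-sided McNemar test against the right-hand window, adjusted p = 0.197 over 18 motifs). In the replicate lists 1.15% ± 0.0898 (SD, n = 3) of summits had a match, and the flanks 1.16% ± 0.0697. The looser form with 1 outer base free was at 10.5% against 9.98% (adjusted p = 1 by the exact test), and 3 scrambled versions of the box were at 1.02%, 1.21% and 1.10% against 1.16%, 0.928% and 1.06%. The difference for the box turned positive, without passing, in the peaks present in all 3 replicate lists (1.49% against 1.045% of flanks, exact adjusted p = 1). It was also positive when the higher-signal peaks were compared with the lower-signal ones (1.21% against 0.530%, exact adjusted p = 0.275), and there the looser form passed (12.35% against 8.56%, exact adjusted p = 0.0322). Against their own flanks the higher-signal peaks showed no excess of the box (1.21% against 1.33%), and the looser form did not pass there (12.35% against 10.83%).

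Of the 23 peaks with a CArG box 15 were in all 3 replicate lists and 10 were at promoters. The strongest, at 2R:13035213-13035463, was intergenic, 11922 bp from CG13323, with CCAATTAAGG at 13035282-13035291. The peak at Fhos held CCAATATTGG at 3L:8766208-8766217 and that at sqh CCTAAAATGG at X:6224360-6224369. Named after their values were seen, Pal1 (a peptide-amidating lyase, in its 5' untranslated region) held CCAAATATGG at 2R:9959960-9959969, at 3.96 ± 0.584 times the median (SD, n = 3), and an intron of sn (fascin, an actin bundler) held CCAAAAATGG at X:7972518-7972527, at 1.34 ± 0.281.

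The motifs of DREF and M1BP were more frequent at the summits of the conservative list than beside them. The site of DREF (a factor of replication and housekeeping promoters), TATCGATA, was at 3.07% of summits against 0.379% of flanks, 8.10 times as often (exact adjusted p = 1.06e-13 by the exact test). That of M1BP (motif 1 binding protein, also of housekeeping promoters), GGTCACACT, was at 1.44% against 0.379% (exact adjusted p = 5.55e-04 by the exact test). DREF passed the threshold in replicates 1 and 2 (exact adjusted p = 1.14e-13 and 2.27e-11) and M1BP likewise (1.75e-05 and 0.0150), but neither did in replicate 3 (0.134 and 0.869, exact tests). In the peaks present in all 3 replicate lists neither passed (exact adjusted p = 0.0669 for DREF and 1 for M1BP), and in the 1320 peaks of higher signal M1BP did not (exact adjusted p = 0.646). At the 1300 summits over 500 bp from any transcript start neither passed, with DREF at 0.385% against 0.423% and M1BP at 0.385% against 0.346%. No background of promoters without peaks was run. The excess of both motifs therefore cannot be told apart from the position of many summits at promoters.

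The other motifs did not pass the threshold. The sites of the GAGA factor (3.90% against 4.09%), Zelda (1.06% against 1.23%), Ets factors (0.379% against 0.322%), Scalloped (0.644% against 0.701%), Mef2 (0.568% against 0.701%), Twist (2.08% against 2.54%), heat shock factor (0.265% against 0.303%) and Grainyhead (0.265% against 0.322%) had adjusted p-values of at least 0.652. BEAF-32 was found at 4 summits. Runs of A (4.39% against 5.30%) and CA repeats (3.75% against 5.38%, exact adjusted p = 0.513) were no more frequent at summits, and in replicate 2 CA repeats passed as rarer (exact adjusted p = 0.00570). In windows reaching 50 bp to each side GAGA sites were rarer at summits (0.833% against 2.20%, exact adjusted p = 7.39e-04), and in windows reaching 200 bp to each side they were more frequent (11.7% against 7.05%, exact adjusted p = 2.09e-06, exact tests).

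**Figure D4:**
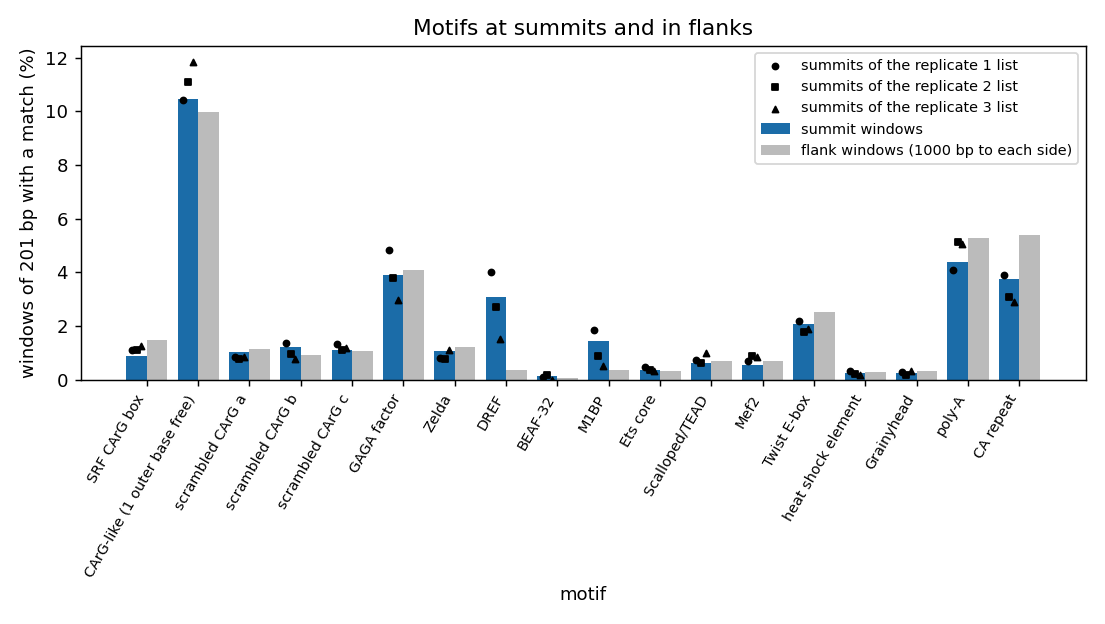
Percent of windows reaching 100 bp to each side of their centre with a match to each motif on either strand, at the summits of the conservative list (blue) and in windows 1000 bp to each side (grey), with points for the summits of the 3 replicate lists. DREF (3.07% against 0.379%) and M1BP (1.44% against 0.379%) exceed the flanks, and the SRF CArG box (0.871% against 1.5%) does not.

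The Mrtf gene itself stood out by its number of peaks. Mrtf (FBgn0052296, 3L:2717615-2766536, minus strand) with 20 kb on each side held 15 conservative peaks where the density of the arm gave 1.82, an 8.25-fold excess (two-sided permutation p = 0.004 against 1000 random windows of the arm). Replicates 1, 2 and 3 had 11, 7 and 6 peaks there, 6.63 ± 2.80 times the density of the arm (SD, n = 3), and the other whole-series lists had 19, 10 and 12. In replicate 2 the excess was at the threshold (permutation p = 0.05, random windows), and with 50 kb on each side it did not pass (permutation p = 0.124). Inside the gene lay 9 of the 15 peaks. The strongest of these, at 3L:2733240-2733575 and 3L:2727061-2727396, were at 1.28 ± 0.348 and 1.15 ± 0.134 times the list median (SD, n = 3) and in all 3 replicate lists. The peak upstream of Mrtf, at 3L:2766777-2767112, lay 409 bp from its start and 54 bp from that of Non2, at 0.870 ± 0.146. The strongest peak of the region, at 3L:2773901-2774236, was 62 bp from a start of CG12093 and overlapped another peak at Atg2 (an autophagy gene), at 1.29 ± 0.387. None of the 15 was among the 25 strongest peaks.

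**Figure D5:**
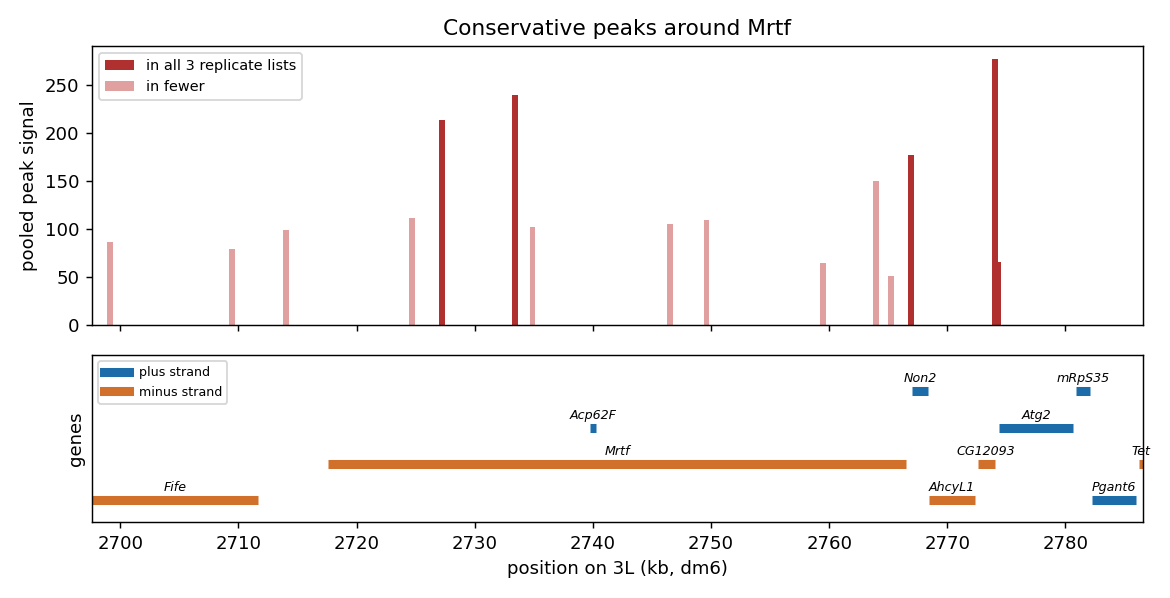
Conservative peaks within 20 kb of Mrtf on 3L, with position in kb (dm6) on the horizontal axis, the authors' pooled peak signal as bar height in the upper panel and genes coloured by strand in the lower panel. Dark bars are peaks in all 3 replicate lists. Of the 15 peaks 9 lie inside Mrtf, 3 at promoters upstream of it and 3 downstream of it away from promoters, and the highest is at CG12093.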

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

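All tests of explanations in this part were chosen after the result was seen, except the CArG tests in wider windows and at distal summits.

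Peaks on unplaced scaffolds, which no comparison used, came to 11 in replicate 1 and 60 in replicate 3, and to 36, 12 and 21 in the largest, middle and smallest of the other whole-series lists. They are listed because each exceeds 3, the limit that a count of 0 allows. In replicate 3 they made up 3.80% of the list, against 0.630% in replicate 1 and 0.126% in replicate 2.

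Ribosomal protein promoters were bound 6.90 times as often in odds as other genes. Signal at every broadly active promoter would raise proteasome genes as well, but the upper 95% limit of their odds ratio was 1.47, below the lower limit of 4.58 for ribosomal proteins. This list of 48 genes was drawn by symbol, and whether members such as Prosalpha1R are active in embryos was not checked. Among genes with an unthresholded peak in all 3 replicates 1 of 16 proteasome genes was bound (odds ratio 0.204). The comparison covers only the list as drawn. Signal at the most heavily transcribed genes of any kind would raise tRNA genes. Among genes with an unthresholded peak in all 3 replicates the upper limit for tRNA genes was 1.12, against a lower limit of 4.68 for ribosomal proteins. The backgrounds were unlike: 7866 entries of all kinds for the 50 tRNA genes, and 6004 protein-coding genes for ribosomal proteins. This comparison covers tRNA genes only and does not stand for heavily transcribed protein-coding genes. Promoters shared with bound neighbours remain open, since among genes without a shared promoter 4 of 21 were bound, with a lower exact 95% limit of 0.857 for the odds ratio, although 41 of 92 were bound when each peak was given only to its nearest start. Transcription level among protein-coding genes may also matter and was not tested, and no biological explanation was tested.

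CArG boxes showed no excess at the summits. Summits placed too imprecisely would give an excess in wider windows, but reaching 200 bp to each side the upper 95% limit of the difference from the right-hand flank was -0.110 percentage points. Promoter peaks hiding distal sites would leave an excess at the 1300 distal summits, where the upper limit was 0.263 points. Weak peaks diluting an excess at strong ones cannot be excluded. In the tenth of peaks with the highest signal 1.89% had a box against 0.947% in the flanks (p = 0.727, exact McNemar test). The upper limit for the difference from the right-hand flank was 2.86 points. The difference was above 0 also in the peaks of all 3 replicate lists (1.49% against 1.045%). In the 1320 peaks of higher signal, however, 1.21% had a box against 1.33% of flanks, with an upper limit of 0.714 points for the difference from the right-hand flank. No biological explanation, such as recruitment by other factors, was tested.

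The cluster of peaks at Mrtf may come from extra copies of the locus, if the transgene spans it. Extra copies would raise the signal of the peaks in the gene that did not reach the list, and their median lay at the 99.8, 85.9 and 99.5 percentile of same-length windows on 3L in replicates 1, 2 and 3. Extra copies therefore cannot be told apart from binding, because 2 replicates go with the explanation, 1 does not, and neither the extent of the transgene nor the control is known here. No biological explanation was tested.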

How the results depend on the processing

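Promoter enrichment (2.20 to 4.82 fold), the overlap of the replicate lists (64.6% to 72.3%) and the Mrtf excess in the conservative list (5.25 fold with 50 kb on each side) kept their direction and their side of the threshold under every alternative run. Added after seeing the data were the settings without transposable elements, with annotated gene starts only and with the 264 peaks of highest signal, and leaving out replicates at Mrtf, in list agreement and in the CArG difference. Without each replicate in turn the mean Spearman correlation ran from 0.677 to 0.783, and the mean number of motifs rarer at summits from 0 (without replicate 2) to 0.5. The X ratio moved to 1.04 (largest other list), 1.27 (smallest list), 1.35 (peaks in all 3 replicate lists) and 1.28 (the 1320 peaks of higher signal). The number of gene lists bound more often went from 4 to 1 in 7 settings, whose odds ratios follow in the order actin filaments, myosin and Hippo, each no longer past the threshold: smallest list 2.47, 2.92 and 2.92, peaks in all 3 replicate lists 1.62, 2.97 and 4.86, peaks of higher signal 2.00, 3.81 and 3.81, 200 bp 2.31, 3.14 and 1.92, genes with an unthresholded peak in all 3 replicates 2.00, 2.46 and 2.05, and annotated gene starts only 1.82, 2.47 and 2.47. The last of the 7 was genes not sharing a promoter, where myosin (14.9), Hippo (2.97) and ribosomal protein genes (3.51) did not pass. Only 2, 6 and 21 genes of these lists remained there. With the largest other list Hippo did not pass (3.44). The nearest start within 10 kb gave 8 lists bound more often, adding actin genes (6.81), integrin adhesion (3.84), sarcomere (3.41) and SRF cofactors (13.6). The number bound less often went from 4 to 2 with an unthresholded peak in all 3 replicates, where tRNA genes (0.425) did not pass and histone genes, with 0 of 111 having such a peak, were not tested, and to 0 among genes not sharing a promoter, where none of the histone, receptor, cuticle or tRNA genes had a peak (odds ratios of 0) and none of these lists passed. The snRNA and snoRNA genes passed as bound less often with the largest other list (0.487), 200 bp (0.0635), the nearest start (0.258) and without transposable elements (0.423). The number of enriched motifs went from 2 to 0 in the peaks of all 3 replicate lists (DREF 1.59 and M1BP 0.299 points above the flank), at summits over 500 bp from a start (M1BP 0.0385) and in the 264 strongest peaks (1.33 and 0.189). It went to 1 in the peaks of higher signal (M1BP 0.568) and with the peaks of lower signal as background, where the looser CArG form passed (3.79). In windows reaching 50 bp to each side 2 motifs were rarer at summits, GAGA (-1.36) and CA repeats (-1.74), and reaching 200 bp GAGA turned to 4.66. DREF turned to -0.530 and M1BP to -1.06 with the peaks of lower signal as background, which by construction compares peaks with peaks, and DREF to -0.0385 at summits over 500 bp from a start. Fewer peaks or genes enter many of these settings, but not that of annotated gene starts only, and otherwise the cause was not tested. A further 16 list and 57 motif values changed sign without passing the threshold on either side. A signal threshold common to the replicate lists was not run because they share no scale. Unknown depth limits all counts of peaks. No paired analysis was possible because the samples form 1 group.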

Other observations

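The tests of short sequences and of GC content were chosen after such sequences had been seen at the summits of all chromosomes, so their held-out chromosomes are not independent of that view. The comparison of start orientation and the GAGA and CA repeat profiles were also chosen after the data were seen, while the test on mitochondrial ribosomal genes without the strongest peaks was set before its result was seen.

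Short sequences recurred at the summits. The 10 8-mers most in excess over the flanks at 946 peaks of chromosome 2 were tested at 1691 peaks of X, 3L and 3R, and 8 of the 10 exceeded the right-hand flank there at an exact McNemar adjusted p under 0.05. AGATGGCG was at 29 of these summits and 1 flank (exact adjusted p = 5.77e-07), GATGGCGC at 24 and 3 (exact adjusted p = 2.46e-04), and both resemble the site of the insulator protein CTCF. TATCGATA, the DREF site, was at 28 and 6 (exact adjusted p = 4.27e-04). The A and T rich CTTTTAAA was at 48 and 16 (exact adjusted p = 2.58e-04) and ATATTAAA at 71 and 33 (exact adjusted p = 4.27e-04). GCTATCGA (21 and 4), AACTATCG (26 and 8) and AGGTGGCG (20 and 4) also passed. GGCGCCAC (17 and 11) and CAGTGGCG (17 and 9) did not pass. The 8 are not separate sequences, since GCTATCGA and AACTATCG share bases with the DREF site, and AGATGGCG with GATGGCGC. Apart from the DREF site they were not tested at distal summits.

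The strongest summits were poor in G and C. In the 61 bp around the summit GC content was 30.8% ± 8.71 (SD) over the 264 peaks with the highest signal and 37.4% ± 11.2 (SD) over the other 2376, while the flanks were at 43.2% and 42.4%. The difference had the same sign on X, 2 and 3, the smallest being -4.61 percentage points, on X. Why was not tested.

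GAGA sites and CA repeats were both rarer at the summit itself than beside it. In windows reaching 25 bp to each side 0.265% of conservative peaks had a site at the summit, 2.69% and 2.77% at 150 bp to the left and right, and 0.795% and 1.10% at 1000 bp. CA repeats were at 0.455% at the summit and at 1.86% and 1.67% at 150 bp to the left and right. Base composition, which differed between summits and flanks, was not taken into account here.

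Mitochondrial ribosomal protein genes lay beside 4 of the strongest peaks, and over the whole list 11 of 73 were bound (odds ratio 1.37, Fisher's exact p = 0.355). With the 25 strongest peaks left out 7 of 73 remained, an odds ratio of 0.828 (95% interval 0.413 to 1.88, Fisher's exact p = 0.853), so a moderate enrichment beyond those peaks is not excluded. The 4 genes beside those peaks stayed among the 73 as unbound, which lowers this odds ratio by construction. The replicate lists bound 12, 15 and 7 of them (Fisher's exact p = 0.0334, 0.0109 and 0.340, unadjusted). These replicate tests kept the 25 strongest peaks, all of which lay in each replicate list. They are therefore not independent of the observation that singled out these genes, and no enrichment can be read from them.

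Of the 1324 promoter summits 35.5% had gene starts on both strands within 500 bp, against at most 32.6% in 100 random sets of promoters. The windows were not alike, since the former were centred on summits, mostly upstream of the start, and the latter on starts of protein-coding genes. No excess can therefore be read from the difference.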
